A study of Mus musculus with 150 samples.

How the data were processed

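The series holds Repli-seq samples of mouse embryonic stem cells with CRISPR deletions or inversions on chromosome 16 or chromosome 8. There are 150 samples, which pair into 75 early and late S-phase fractions. Per the submitters' processing notes, reads were aligned to mm10 and Bowtie2, SAMtools and bedtools were used; their versions, the smoothing, the filters and the scaling are not given in the sources used here. The deposited values are a replication timing score with 1 value per position, 5 kb apart, at 19641 positions of chromosome 16 and 25880 of chromosome 8. The authors combined the early and late fractions into this score, and positions without a value are blank. Between 18837 and 19019 chromosome 16 positions and between 25223 and 25240 chromosome 8 positions of a column hold a value. Values ran from -20.11 to 18.37 on chromosome 16 and from -4.21 to 4.77 on chromosome 8. Every column has an interquartile range of 4.60, and the non-hybrid columns share their quartiles, so the columns were scaled before deposit. The log base is not given in the sources used here, so differences are in units of the score and are not fold changes. The design had assumed log2 early to late ratios; the score is continuous and has both signs, and the same limma test was used. Read depth is unknown, so no counting interval can be given, and the spread between clones sets the precision.

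Samples were grouped by the genotype and background in the labels. Hybrid profiles have 1 column per allele: svim and cast in cas/129 cells, C57BL and svim in v6.5 cells. The labels do not name the edited allele, so both are reported and neither is called edited. A further 6 columns of the chromosome 16 table, 4 named F121.9 nesc and 2 named F121.9 NPC, match no listed sample and were not used. Their names give no edit, and whether they are unedited cas/129 profiles is not stated. Repeat libraries of a clone were averaged, so n counts clones. The groups, the 5 comparison clones, the regions, the gene lists, the tests and the alternatives were chosen before the data were examined, except where the text says otherwise. Non-hybrid cells and cas/129 cells were kept in different media, so background and culture cannot be separated, and no test spans them.

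The chromosome 16 domain runs from 48190131 to 48620367, from the left end of the 145kdel to the right end of interval c. The chromosome 8 region runs from 43076771 to 43432339, the span of both deletions with 100 kb on either side. A domain value is the mean score over its positions. Positions inside the deletions of a genotype, and of the clones compared with it, were left out of all profiles in that comparison. Windows of 50 kb were tiled over the chromosome and kept where at least 50 percent of their positions were left. Windows over 2 Mb from every labelled edit end count as far.

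Each genotype was compared with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all windows of the chromosome plus the domain, and a threshold of 0.05. Each cas/129 fit held the genotype and the 5 comparison clones. Non-hybrid profiles were fitted together with 1 group per genotype, so that the spread came from the 2 genotypes with 2 clones. Lone profiles were assumed to vary like them. Chromosome 8 genotypes were compared with each other, because no unedited profile is listed. Departures from additivity were contrasts in a fit of the a, b, c, ab, ac, bc and abc deletions with the comparison clones. Exact two-sided permutation tests over clones were added for the domain and for svim minus cast where a genotype has at least 2 clones. They cannot give a p below 0.0476 with 2 against 5 clones, 0.0179 with 3 against 5 and 0.0079 with 4 against 5. The v6.5 clones and the NPC profile have no test.

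Gene scores are means over the annotated gene body (GRCm38, the mm10 build). Genes were tested with limma as the windows were, over 675 to 679 genes of chromosome 16 and 1041 to 1043 of chromosome 8. The lists fixed beforehand were domain genes, flank genes, and early and late control genes elsewhere, for each chromosome. Guca1c of the right flank list was not found in the gene table. Counts are given over all genes tested and adjusted over the list alone. Named items were fixed beforehand: every labelled genotype with its domain value, the 4 intervals, the genes of the lists, the ends of the run of changed windows that touches the domain, and the 3 far windows with the largest change. Clones are named where they differ from the other clones of their genotype by more than the comparison clones' range.

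The procedure was tested on simulated data with 200 changed windows before it was applied. With 2 clones against 5 on chromosome 16 it recovered 26.9, 86.6 and 100 percent of windows shifted by 1, 2 and 4. With 1 clone against 5 it recovered 1.5, 28.4 and 92.4 percent. With 1 non-hybrid profile against 46C it recovered 1.5, 20.9 and 66.7 percent, and for the ab.del departure 3, 52.2 and 93.9 percent. A lack of calls therefore cannot exclude shifts of 1 in these designs, or of 2 in the last 3. The alternatives were rescaled profiles (median and interquartile range set on the chromosome outside 5 Mb around the edits), quantile normalization, windows of 25 and 100 kb, narrower and wider domains and 50 kb sides on chromosome 8. Further alternatives kept the positions of deletions, left out 25 kb beside them, took other comparison profiles, used 1 fit over all cas/129 genotypes, counted repeats as separate samples, and used eBayes with trend and robust settings. Each clone was also left out in turn, and the chromosome 8 alleles were averaged. Added after the values were seen were the adjustment over the domain tests of a family alone and the comparison of changed windows by length in kb, and the correlation over genotype means. Correlations used 100000 permutations, and other splits of the clones were drawn up to 100 times. Figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.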

Results

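Replication timing was measured by Repli-seq in mouse embryonic stem cells (mESC). Newly made DNA was labelled with BrdU, cells were sorted into early and late S phase, and the labelled DNA of both fractions was sequenced. The 150 samples form 75 early and late pairs, and each pair gave 1 profile of a replication timing score along chromosome 16 or chromosome 8 (mm10). A higher score means earlier replication: in 135 of 135 value columns, genes listed beforehand as early replicating scored above those listed as late. The edits are deletions and inversions, most of them in a chromosome 16 domain that holds Dppa2 and Dppa4, SAP-domain proteins of pluripotent cells, and Morc1, an ATPase needed to silence transposons in the male germ line. The other edits lie on chromosome 8 around Zfp42, which encodes the pluripotency marker Rex1, and the tripartite-motif-like genes Triml1 and Triml2. Non-hybrid cells gave 15 profiles in 12 groups, with the unedited 46C line among them and no separation of alleles. Hybrid cas/129 cells gave 50 mESC profiles for chromosome 16, from 43 clones in 26 groups of 1 to 4 clones. Every cas/129 profile has a score for the svim allele (the 129 parent) and the cast allele. There were also 3 clones of the v6.5 hybrid background, 1 profile titled NPC (neural progenitor cell), and 6 chromosome 8 profiles, 2 clones for each of 3 genotypes. Read depth is unknown for every sample.

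The edits of chromosome 16 were compared over a domain from 48190131 to 48620367, set from the labelled edit ends. Interval a (48308399 to 48311882) overlaps the left end of Dppa2, and interval b (48396806 to 48437301) the left end of Morc1. Interval c (48581359 to 48620367) lies inside Morc1. The 4kdel interval (48280115 to 48284009) overlaps the left end of Dppa4. No unedited cas/129 clone is listed among the samples, and 6 columns with F121.9 names, which name no edit and match no listed sample, were left out, so 5 clones edited outside these 4 intervals served for comparison: 30kdel B11 and C2, 29kdel D8, 14kdel D11 and 24.5kinv 3. In these clones the domain replicated early on both alleles, with a mean score of 2.09 ± 0.45 (SD, n = 5) on svim and 2.55 ± 0.56 (SD, n = 5) on cast. Of their edits, only the 30kdel lies outside the domain. The 24.5kinv starts at the right end of interval a (48311882), inside Dppa2. The 14kdel ends at the left end of the 4kdel interval (48280115). Clone 24.5kinv 3 had the lowest domain score of the 5 on each allele, 1.63 on svim and 1.72 on cast. The 7 pairs of repeat libraries of a clone correlated along the chromosome at 0.94 to 1.00 (across positions, which are not independent), and the SD between repeats in the domain was 0.28 on svim and 0.47 on cast. The labels do not say which allele carries an edit. Of the 49 hybrid deletion profiles with positions inside the edit, 42 had blank positions there in the svim column alone, 1 in cast alone (680kdel 79), 2 in C57BL alone and 1 in both columns (RexTrim D8, where 1 of 7 cast positions was blank), and 3 (a.del) had no blanks. The svim columns of ab.del, ac.del and abc.del still held a value at 1 position inside their edits. Replicates are clones or libraries whose independence is only as labelled, so the p-values measure the spread between these samples.

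**Figure D1:**
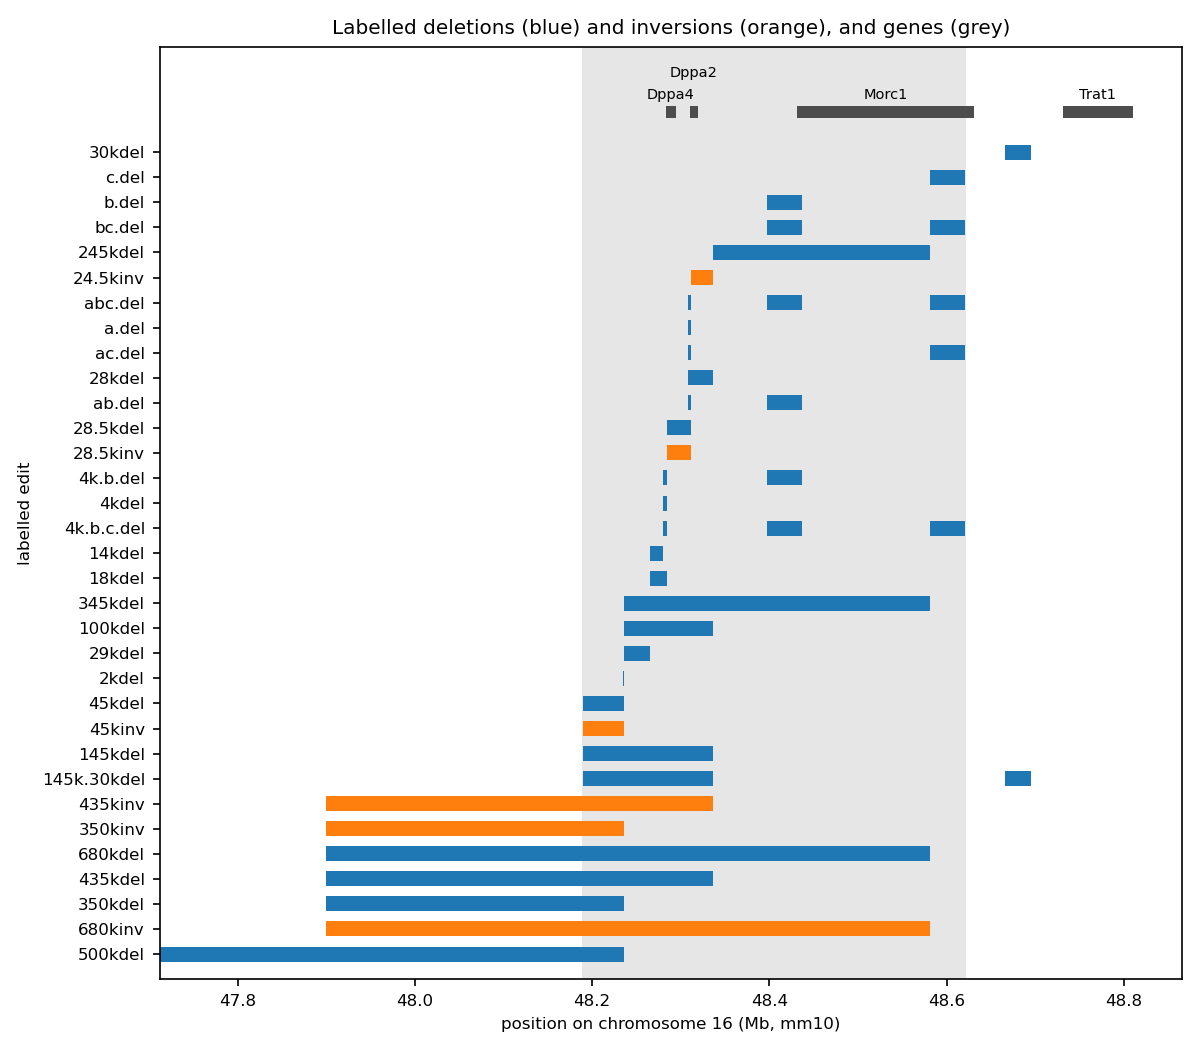
Labelled deletions (blue) and inversions (orange), 1 line per edit, and genes (dark grey) against position on chromosome 16 in Mb (mm10), with the domain shaded. Intervals a, b and c lie apart within the domain and are removed singly and together.

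Removing intervals a, b and c together moved the whole domain from early to late replication on the svim allele. The domain scored -2.81 in the abc.del clones and 2.06 in the comparison clones, a difference of -4.88 ± 0.39 (SE, n = 2 and 5 clones), with A6 at -2.72 and E2 at -2.90. Pairs of deletions that include a also made the domain later: the difference was -2.86 ± 0.38 in ab.del (n = 2) and -2.93 ± 0.48 in ac.del (n = 2). On cast, the other allele of the same clones, the differences were 0.05 in abc.del, 0.05 in ab.del and -0.52 in ac.del (-0.07 without H8). The limma adjusted p on svim was 4.51e-06 for abc.del, 0.0012 for ab.del and 0.0041 for ac.del, with both clones lower in each. The exact two-sided permutation p over clones was 0.0476 for each, the smallest that 2 against 5 clones allows. The change reached past the domain: runs of later 50 kb windows spanned 48050001 to 48900000 in abc.del, 48050001 to 48850000 in ab.del and 48100001 to 48850000 in ac.del. On cast, limma called 0 windows in the 3 genotypes, with 9, 12 and 12 windows at an unadjusted p under 0.05. The ac.del clones differed from each other by more than the comparison clones' range, E4 at -0.0011 and H8 at -1.63. Without H8 the ac.del difference was -2.11 (adjusted p 0.5381) with 0 kb of changed windows, against 650 kb with it. Without D10 the ab.del difference was -2.74 (adjusted p 0.072), and its 650 kb of changed windows became 250 kb without D10, 300 kb without D12 and 400 kb without comparison clone 30kdel B11 or C2. When the columns were rescaled on the rest of the chromosome, abc.del stayed past the threshold, while ab.del (-2.47, adjusted p 0.6043) and ac.del (-2.95, adjusted p 0.1912) did not.

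Gene scores average the same positions as the domain and windows. The calls of domain and flank genes below thus describe the same change gene by gene and are not separate support. All 3 genes of the list of domain genes fell on svim in abc.del, ab.del and ac.del: in abc.del the differences were -4.66 for Dppa4, -4.83 for Dppa2 and -5.06 for Morc1 (limma adjusted p 6.38e-06, 6.38e-06 and 2.05e-06, lower in 2 of 2 clones). In ab.del they were -3.64 for Dppa4, -3.49 for Dppa2 and -2.30 for Morc1, and in ac.del -2.56, -2.60 and -3.09 (adjusted p at most 0.0132, lower in 2 of 2 clones). Of the 13 measured genes of the right flank list, 4 fell in abc.del: Trat1, an adaptor associated with the T-cell receptor (-3.33, adjusted p 5.97e-05), and the genes of the resistin-like secreted proteins, Retnlb (-2.85), Retnla (-2.51) and Retnlg (-2.15). In ab.del and in ac.del 3 of the 13 fell, namely Trat1, Retnlb and Retnla. Adjusted over the list alone, the flank counts were 6 in abc.del, 6 in ab.del and 7 in ac.del. Over the 679 genes tested, 7 fell in abc.del, 7 in ab.del and 6 in ac.del. Of the control genes elsewhere on chromosome 16, limma called 0 over 71 comparisons; adjusted over the list alone, 1 early control gene passed in a.del on each allele, with 1 domain gene lower in a.del on cast. In abc.del, Dppa4, Dppa2, Morc1 and Trat1 kept their calls under the rescaling, the quantile normalization and each clone left out. Retnlb lost its call without E2 (adjusted p 0.0511), Retnla without E2 (0.1993) and Retnlg without E2 (0.6757), A6 (0.1019) or comparison clone 30kdel B11 or C2 (0.0513 and 0.079); rescaling ended those of Retnla (0.0768) and Retnlg (0.2079). Rescaling ended every named gene call in ab.del (0.3939 to 0.8621) and ac.del (0.3218 to 0.4142), and quantile normalization those of Trat1, Retnlb and Retnla in ab.del (0.2931 to 0.3689) and of Dppa4, Dppa2 and Retnla in ac.del (0.0624 to 0.0973). The differences kept their sign under rescaling: Dppa4 was at -3.23 in ab.del and -2.59 in ac.del, and Morc1 at -1.92 and -3.11. In ab.del, Morc1, Trat1, Retnlb and Retnla lost their calls without D10 (0.3822 to 0.927) or D12 (0.1186 to 0.4018), Trat1, Retnlb and Retnla without comparison clone 30kdel B11 (0.0611 to 0.1518), and Retnlb and Retnla without C2 (0.084 and 0.1383); Retnla also lost its call with 25 kb beside deletions left out (0.0568). All 6 named ac.del genes lost theirs without H8 (0.9008 to 0.999) or comparison clone 30kdel C2 (0.0634 to 0.1936), and Retnla without 30kdel B11 (0.0756).

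**Figure D2:**
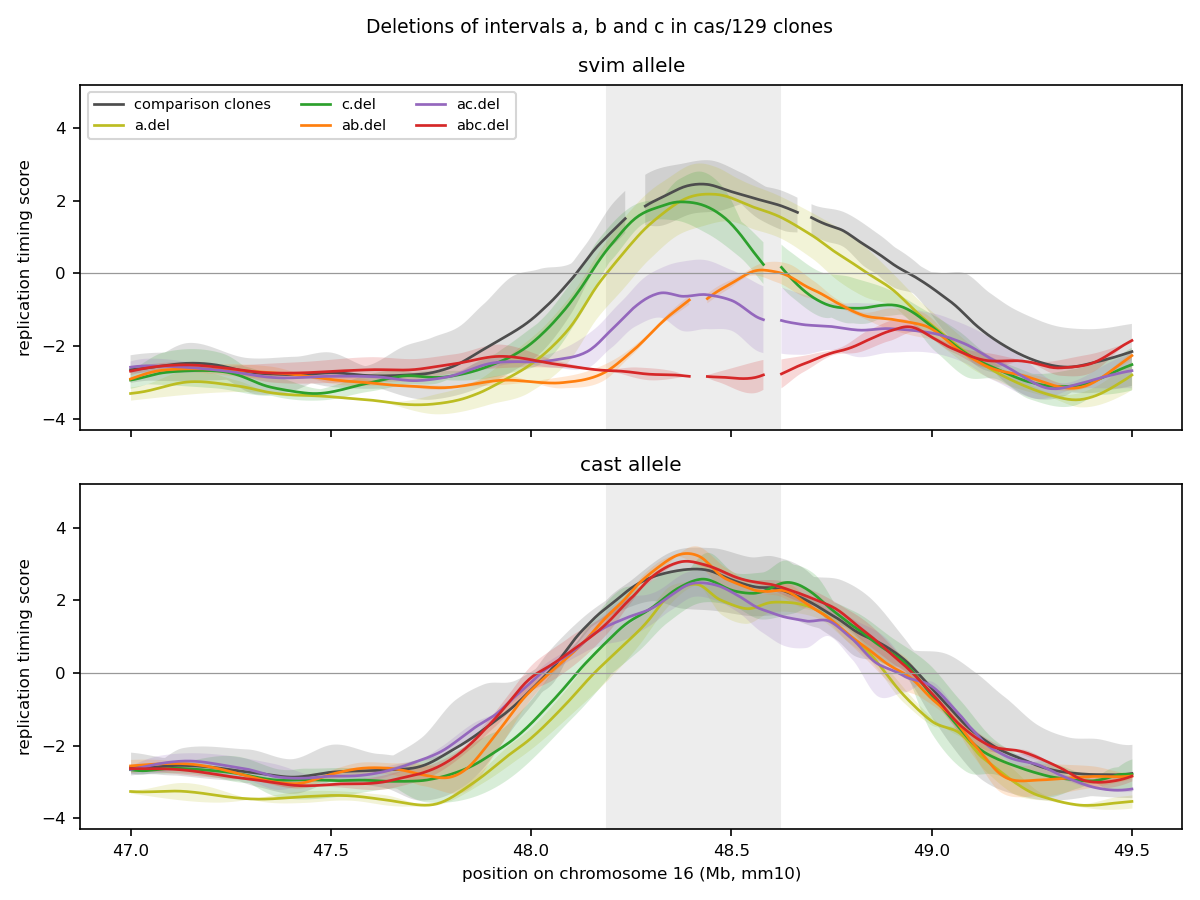
Replication timing score against position on chromosome 16 in Mb, for the svim and cast alleles; lines are means over clones, bands span the lowest to the highest clone, and gaps are positions left out because an edit removed them. On svim the abc.del line stays near -2.81 across the shaded domain where the comparison clones average 2.06, and on cast the lines overlap.

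With interval c alone lost, the right side of the domain and its flank were later on svim in the profiles as deposited. The mean of the whole domain did not pass the limma threshold. In c.del, 5 svim windows from 48550001 to 48850000 became later (limma). Trat1 (-2.12, limma adjusted p 0.0073) and Retnlb (-1.85, adjusted p 0.025) fell, each lower in 4 of 4 clones. Both genes lie within these windows, so their calls are not separate support. Dppa4 (-0.17), Dppa2 (-0.22) and Morc1 (-1.08) did not pass over all genes tested. Adjusted over the list alone, 1 domain gene and 7 flank genes were lower. The domain mean was 1.46 against 2.11, a difference of -0.65 ± 0.32 (SE, n = 4 and 5 clones; limma adjusted p 0.9455, exact two-sided permutation p 0.0476), and the smallest p this design allows is 0.0079. On cast the domain difference was -0.46 (limma adjusted p 0.9978). Limma called 0 cast windows, with 89 at an unadjusted p under 0.05, beside 83 on svim. Svim minus cast of the domain did not set c.del apart from the comparison clones (exact permutation p 0.5873). The c.del windows were lost under rescaling and under quantile normalization (0 kb under each). They were also lost without A12, without B11 and without comparison clone 30kdel C2 (0 kb each), and shrank from 250 to 100 kb without C9 or without comparison clone 30kdel B11. Rescaling ended the calls of Trat1 (adjusted p 0.6895) and Retnlb (0.7395), as did quantile normalization (0.0879 and 0.1318). Their differences were still -1.82 and -1.55 under rescaling and -1.73 and -1.47 under quantile normalization. Trat1 was also no longer called without A12 (0.0536) or B11 (0.0665), and Retnlb without A12, B11 or C9 (0.1567, 0.1315 and 0.0851) or without comparison clones 30kdel B11 or C2 (0.1075 and 0.1305).

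The other deletions of these intervals gave smaller differences on svim, none past the limma threshold. Against the comparison clones the domain differed by -0.38 in a.del (n = 2), -0.36 in b.del (n = 2) and -1.08 in bc.del (n = 2; adjusted p 0.9988). The exact two-sided permutation p of bc.del was 0.0476, the smallest possible, with 2 of 2 clones lower. Removing the 4kdel interval gave -0.71, removing it with b gave -0.46 (n = 2 each), and removing it with b and c gave -1.92 (1 clone, G12; adjusted p 0.865). On cast the differences were -0.71 in a.del, -0.10 in b.del, 0.13 in bc.del, 0.18 in 4kdel, -0.69 in 4k.b.del and -0.34 in 4k.b.c.del, none past the limma threshold. In a.del and 4k.b.del cast thus fell by more than svim. The smaller svim values moved with single clones. The a.del difference was -1.16 without 53 and 0.39 without G5, that of 4kdel -0.31 without G4 and -1.11 without C6, and that of 4k.b.del -0.22 without B1 and -0.70 without B4. Without comparison clone 30kdel C2 the b.del difference was -0.20. Without comparison clone 24.5kinv 3 the 4k.b.c.del difference became -2.04 (adjusted p 0.0212). Limma called 0 windows in a.del on either allele, with 256 on svim and 226 on cast at an unadjusted p under 0.05. On svim this became 950 kb without comparison clone 14kdel D11 and 800 kb without 24.5kinv 3. Without 24.5kinv 3, 4k.b.del had 2100 kb on svim and 500 kb on cast in place of 0, and 4k.b.c.del had 500 kb on svim in place of 0, as well as 350 kb without 14kdel D11 and 200 kb without 29kdel D8. Adjusted over the list alone, 3 domain genes and 5 flank genes were lower in 4k.b.c.del, and 1 and 4 in bc.del; over all genes tested, limma called 0 in both. The a.del clones differed on svim by more than the comparison clones' range, clone 53 at 2.48 and G5 at 0.93.

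**Figure D3:**
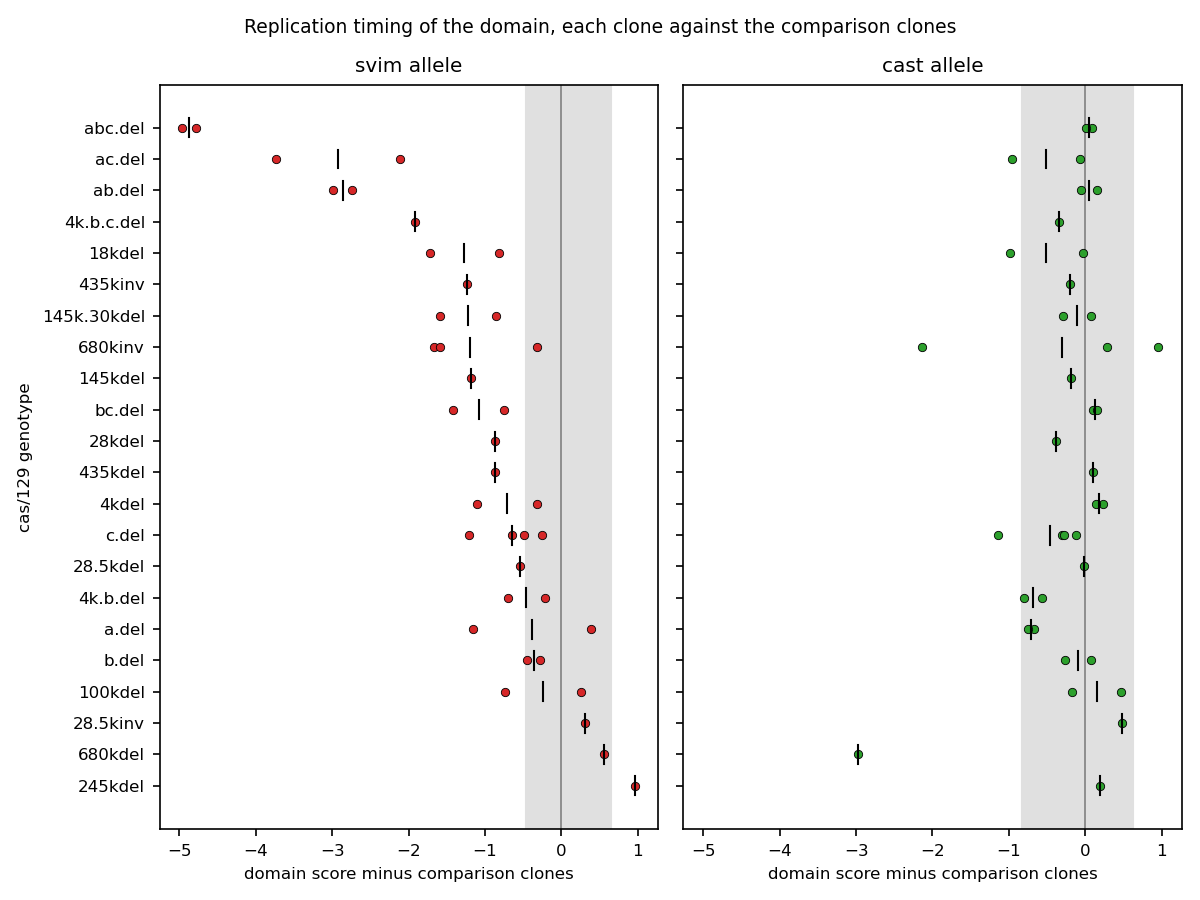
Domain score minus the mean of the comparison clones for each clone (points), with the genotype mean (black bar), on the svim and cast alleles of cas/129 clones; shading spans the comparison clones. On svim abc.del (-4.88), ac.del (-2.93) and ab.del (-2.86) lie lowest; on cast the lowest point is 680kdel 79 (-2.97).

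Comparing the alleles within each clone removes differences between libraries that both alleles share. Svim minus cast was -0.46 ± 0.34 (SD, n = 5) in the comparison clones. It was -5.41 in abc.del, -3.38 in ab.del, -2.88 in ac.del, -1.69 in bc.del, -1.50 in 145k.30kdel and -1.36 in 4kdel, each with 2 of 2 clones below the comparison mean. The exact two-sided permutation p was 0.0476 for each of these 6, the smallest possible. After Benjamini-Hochberg adjustment over 13 tests it was 0.1031, so none passed the correction. A p of 0.0476 could pass there only if all 13 tests gave that p or a smaller one. The failure was thus set by the number of clones and decides nothing. In 18kdel svim minus cast was -1.22 (exact permutation p 0.0952, adjusted 0.1768), in c.del -0.65, with C6 at 0.19, C9 at -0.42, A12 at -0.84 and B11 at -1.55, and in a.del -0.13, with clone 53 at 0.60 and G5 at -0.87. Relative to the comparison clones, the c.del value was -0.18 and ran from -0.46 to 0.11 with 1 clone left out, and the 4kdel value was -0.89, and -0.54 without G4. Genotypes with 1 clone had no permutation test: 4k.b.c.del, 435kinv, 145kdel and 435kdel lay -4.77, -3.06, -2.80 and -2.75 comparison SDs from the comparison mean. The 680kdel clone 79 lay 6.35 SDs to the other side, with svim minus cast at 3.13 over the 8 domain positions outside its deletion.

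Whether the deletions act additively was tested as the combined difference minus the sum of the single ones. On svim the combinations differed from the sums by -2.22 ± 0.68 in ab.del, -1.83 ± 0.63 in ac.del and -3.43 ± 0.83 in abc.del (SE), and bc.del departed by -0.05 ± 0.63. With all windows of the chromosome in the correction, the limma adjusted p was 0.6186, 0.2386 and 0.1198 for ab.del, ac.del and abc.del, so no departure passed. With the correction over the domain tests alone, a choice made after the values were seen, ab.del (0.0157), ac.del (0.0232) and abc.del (0.0044) passed. The abc.del departure was -4.22 (adjusted p 0.0428) without a.del G5 and -2.64 without a.del 53. That of ab.del was -3.01 without a.del G5 and -1.43 without a.del 53, and that of ac.del -1.04 without a.del 53 or ac.del H8. Limma called 0 windows in these contrasts (54 to 323 on svim and 64 to 323 on cast at an unadjusted p under 0.05), which became 100 kb for abc.del on svim without a.del G5 and 400 kb for ac.del on cast without bc.del B3 or D12. On cast the departures were 0.98 in ab.del, 0.73 in ac.del, 0.73 in bc.del and 1.44 in abc.del, none past the threshold. That of ac.del was 0.27 without ac.del E4 and 1.19 without H8, and under rescaling it was -0.05. All 3 domain genes departed downward on svim in ab.del, ac.del and abc.del, and 1 flank gene upward on svim and 2 domain genes upward on cast in abc.del, adjusted over the list alone; over all genes tested, limma called 0.

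The other edits of the domain gave a mixed picture in cas/129 clones, and limma called no domain difference among them. On svim the domain differed by -1.27 in 18kdel (n = 2), -1.22 in 145k.30kdel (n = 2), -1.19 in 145kdel, -0.87 in 28kdel, -0.55 in 28.5kdel, -0.24 in 100kdel (n = 2), -0.87 in 435kdel and 0.97 in 245kdel. The exact two-sided permutation p was 0.0476 for 18kdel and for 145k.30kdel, with 2 of 2 clones lower in each. The 100kdel clones went opposite ways (B6 -0.73, C3 0.26), and 18kdel was -0.82 without D6. Adjusted over the list alone, 3 domain genes were lower in 18kdel, 2 in 435kinv, 2 in 680kinv and 1 in 145k.30kdel, with 1 flank gene lower in 680kinv on svim and in 680kdel on cast, and over all genes tested limma called 0 in each. In the 680kdel clone 79 the later allele was cast (-2.97, adjusted p 0.5986) and svim stood at 0.56; cast is also the column without values inside that deletion. Without comparison clone 24.5kinv 3, the 680kdel cast difference was -3.16 (adjusted p 0.0305). The cas/129 680kdel values cover the 8 domain positions outside the deletion, where those of 680kinv cover 77. The inversion clones 680kinv B10 and C5 were later on svim (0.42 and 0.50) than on cast (3.50 and 2.83), and clone 80 later on cast (0.42) than on svim (1.77). The mean 680kinv difference on svim was -1.19 (n = 3; limma adjusted p 0.8399, exact two-sided permutation p 0.0357, smallest possible 0.0179). Relative to the comparison clones, svim minus cast was -0.89 in 680kinv (exact permutation p 0.375), -2.25 without clone 80 (0.0476) and -0.03 without B10. Taken without sign, it was 1.79 (exact permutation p 0.0179), and 0.18 over a wider domain (0.4821). The 435kinv clone differed by -1.24 on svim and the 28.5kinv clone by 0.31. Over the 22 genotypes, 18 on svim had 0 changed windows (limma; 6 to 256 at an unadjusted p under 0.05), and all 22 had 0 on cast (0 to 226). Leaving out comparison clone 24.5kinv 3 gave 435kdel 200 kb and 435kinv 350 kb on svim and 680kdel 50 kb on cast in place of 0, and leaving out 680kinv 80 gave 680kinv 550 kb on svim. No window over 2 Mb from the edits was called in a cas/129 comparison.

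In non-hybrid cells the 345 kb and 680 kb deletions went with late replication of what was left of the domain. After the 345kdel, which removes 48235964 to 48581356, the domain scored -2.30 against 1.74 in 46C, a difference of -4.03 ± 0.43 (SE, 1 profile each). The 680kdel clones scored -1.56 against 1.92, a difference of -3.48 ± 0.46 (n = 2 and 1), and 435kdel differed by -1.80 ± 0.53. These values cover the domain positions outside each deletion, 17 in 345kdel, 8 in 680kdel and 57 in 435kdel. The limma adjusted p was 0.0666 for 345kdel, 0.085 for 680kdel and 0.9991 for 435kdel, and the spread came from the 2 genotypes with 2 clones. With the correction over the domain tests alone, a choice made after the values were seen, these became 5.51e-04, 9.90e-04 and 0.0469. With 100 kb windows 345kdel and 680kdel also passed (0.0323 and 0.0392). The other edits differed by less: 245kdel by 0.76, 100kdel by -0.48, 350kinv by 0.28, 45kinv by 0.21, 45kdel by 0.15, 350kdel by -0.15, 500kdel by -0.01 and 2kdel by -0.0011.

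**Figure D4:**
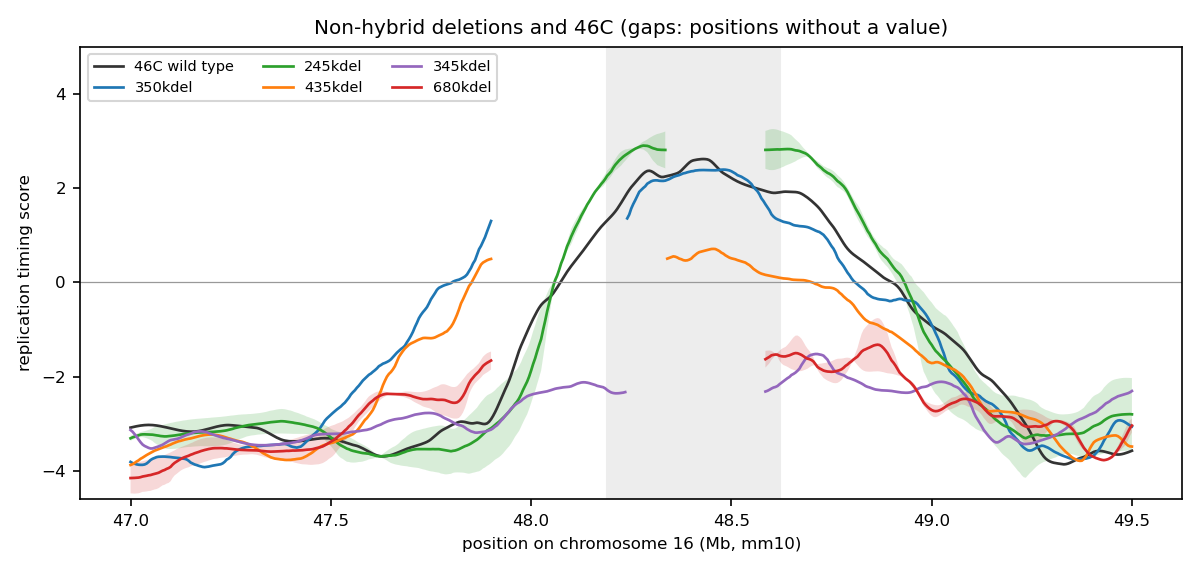
Replication timing score against position on chromosome 16 in Mb for 46C and 5 non-hybrid deletions; lines are means over profiles, bands span both clones where there are 2, gaps are deleted sequence, and the domain is shaded. Within the shaded domain the 345kdel and 680kdel lines lie below zero, where 46C is above 1.

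Single genes outside the non-hybrid deletions passed the threshold, some beside a deletion and some farther along the chromosome. The spread came from the 2 genotypes with 2 clones, 245kdel and 680kdel. For 345kdel and 500kdel, 1 profile against 1, the p-values hold only if these profiles vary like those clones. In 345kdel the values that passed were Trat1 (-2.87, limma adjusted p 0.0227), Retnlb (-2.63) and Retnla (-2.57, 0.0277 each), Retnlg (-2.43, 0.0394) and, farther right, Cd47, an integrin-associated protein (1.93, 0.0277); rescaling ended the call of Retnlg (0.0688). The flank list thus held 4 lower and 1 higher gene of 13, and 5 and 3 adjusted over the list alone. Over the 676 genes tested, 26 higher and 9 lower genes passed in 345kdel under that assumption. In 500kdel 2 flank genes and in 100kdel 1 were higher adjusted over the list alone, and in 435kdel 1 domain gene was lower. In 680kdel Trat1 fell (-2.79, adjusted p 0.0097, lower in 2 of 2 clones), a call that ended without clone 13 (0.4048) or clone 16 (0.3623); 7 flank genes passed adjusted over the list alone. In 245kdel the cell adhesion gene Nectin3 rose by 2.08 (adjusted p 0.0302, higher in 2 of 2 clones), and 6 flank genes were higher adjusted over the list alone. Nectin3 and Cd96 lie left of the domain although both were listed with the right flank, so the flank counts can mix both sides. Nectin3 ends at 46498535, while the 245kdel starts at 48336437. In the 500kdel non-hybrid profile, where the deletion removes the left part of the domain and sequence beyond it, the label reads heterozygous, unlike the homozygous labels of the other non-hybrid edits, although every position inside it is blank. There 2 windows left of the deletion, 47600001 to 47650000 and 47650001 to 47700000, scored higher than in 46C by 4.06 and 4.82 (adjusted p 0.0378 each, under the same assumption). The other 10 non-hybrid genotypes had 0 changed windows (limma; 4 to 253 at an unadjusted p under 0.05). In 245kdel this became 17050 kb without clone 25 and 2850 kb without clone 28.

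An inversion keeps the sequence that a deletion of the same interval removes. No inversion differed from its deletion past the limma threshold in the rest of the domain. The comparison was 3 clones against 1 for 680 kb and 1 against 1 for the other intervals, with SEs from 0.46 to 0.99. Such numbers cannot show that an inversion and its deletion have equal scores. Inversion minus deletion was 0.86 on svim and 0.52 on cast for the 28.5 kb interval, -1.46 (adjusted p 0.9997) and 2.49 for the 680 kb interval, and -0.21 on both alleles for the 435 kb interval. Over all genes tested limma called 0 in each; adjusted over the list alone, 6 of 13 right flank genes were lower on svim in 680kinv than in 680kdel. For 680 kb the values cover 8 domain positions, and the later alleles do not match: the later allele is cast in 680kdel 79 and 680kinv 80, and svim in 680kinv B10 and C5. In non-hybrid cells it was 0.07 for 45 kb and 0.43 for 350 kb. Limma called 0 windows in each, with 1 to 18 on svim, 0 to 6 on cast and 1 to 24 in non-hybrid cells at an unadjusted p under 0.05.

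The v6.5 clones, from a C57BL and 129 hybrid, were described without a test because each genotype has 1 clone. In 100kdel C6 the domain scored 1.26 on C57BL and 1.86 on svim, and in 18kdel H5 1.31 and 1.84. The 18kdel H5 svim column stands apart: its early control genes average -0.65, where those of its C57BL column average 2.77. In 435kinv A4 it scored 2.52 on C57BL and 1.52 on svim, a difference of 1.01 that became -0.04 over a wider domain. The profile titled NPC, whose cell type label reads mESC, came from 100kdel clone C3. There the domain was late on both alleles, -4.29 on svim and -3.91 on cast; minus the mESC profiles of the same clone, the differences were -6.65 and -6.91.

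On chromosome 8, removing Rex1 and Trim sequence together made the region late on the svim allele, and removing Rex1 sequence alone gave a level between. The Rex1 deletion (43302260 to 43332339) overlaps Zfp42, and the Trim deletion (43176771 to 43181949) overlaps the ends of Triml1 and Triml2. Over 43076771 to 43432339 the region scored 1.60 in Trim, -0.72 in Rex1 and -2.77 in RexTrim clones on svim (n = 2 each). The differences were -4.37 ± 0.29 for RexTrim minus Trim, -2.32 ± 0.29 for Rex1 minus Trim and -2.05 ± 0.29 for RexTrim minus Rex1 (SE; limma adjusted p 9.73e-06, 0.0032 and 0.0072, with both clones of the first genotype lower than both of the second). On cast the region scored 1.40, 1.96 and 1.04, with differences of -0.36, 0.55 and -0.92, none past the threshold. The sign of RexTrim minus Trim turned without Trim E9 (0.19) and that of Rex1 minus Trim without Trim D9 (-0.0015). RexTrim minus Rex1 was -0.57 without RexTrim D8, and after rescaling it was -1.65 (adjusted p 0.0303). Runs of later svim windows through the region spanned 42850001 to 43850000 for RexTrim minus Trim, 42900001 to 43850000 for Rex1 minus Trim and 43000001 to 43450000 for RexTrim minus Rex1. No unedited chromosome 8 profile is listed, so each value is relative to another deletion. Without Rex1 D1, RexTrim minus Rex1 was -1.94 (adjusted p 0.0554), and without Trim E9, Rex1 minus Trim was -2.33 (0.0683).

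**Figure D5:**
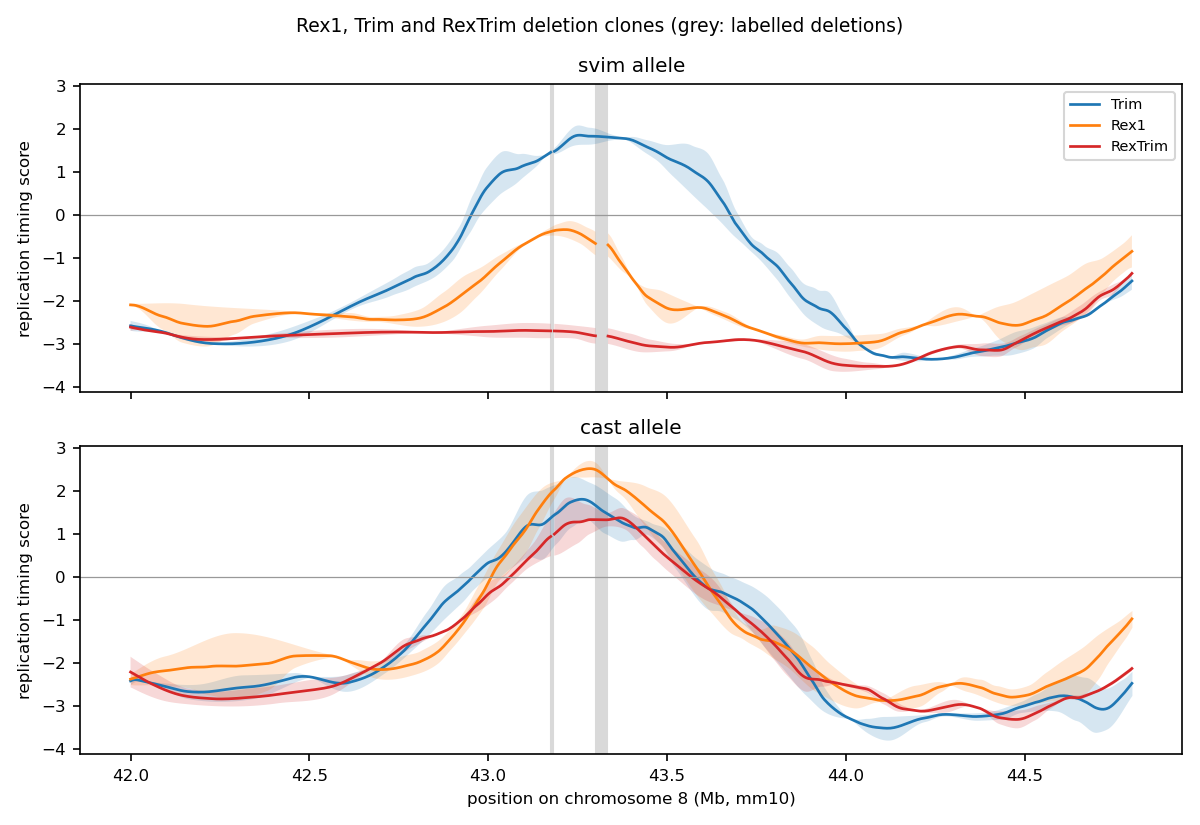
Replication timing score against position on chromosome 8 in Mb for Trim, Rex1 and RexTrim clones on both alleles; lines are means of 2 clones, bands span both, and grey bars mark the labelled deletions. On svim the region means are 1.60, -0.72 and -2.77, and on cast all 3 genotypes are above zero there.

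All 3 genes of the chromosome 8 domain list fell on svim in each comparison. They lie within the region, so their scores average positions already in its mean and are not separate support. RexTrim minus Trim was -4.63 for Zfp42, -4.03 for Triml1 and -4.20 for Triml2 (limma adjusted p 1.27e-05 each, lower in 2 of 2 clones), and Rex1 minus Trim was -2.48, -1.79 and -1.86 (0.0029, 0.0031 and 0.0031). RexTrim minus Rex1 was -2.16, -2.24 and -2.34 (0.009, 0.0024 and 0.0024), and without Rex1 D1 the adjusted p of Zfp42 there was 0.0591. Of the flank list, the testis-expressed ADAM genes Adam26a, Adam26b and Adam34 were 3 of 10 that fell, with differences of -4.04, -4.31 and -3.21 for RexTrim minus Trim and -3.19, -3.44 and -2.61 for Rex1 minus Trim. Adjusted over the list alone the counts were also 3, and on cast 2 flank genes were higher for Rex1 minus Trim and 1 lower for RexTrim minus Rex1. Over all genes tested on svim, 46 were higher and 164 lower of 1041 for RexTrim minus Rex1, 17 and 33 of 1041 for Rex1 minus Trim, and 0 and 8 of 1043 for RexTrim minus Trim; on cast there were 0. With both alleles averaged, these 6 genes lost their calls for Rex1 minus Trim (adjusted p 0.0649 to 0.1707), and all but Zfp42 for RexTrim minus Trim (0.095 to 0.2285). In RexTrim minus Rex1, 4 control genes elsewhere on the chromosome also fell: Calr (-1.12), Dnase2a (-0.93), Gins2 (-0.77) and Sntb2 (-1.16; adjusted p 0.0371, 0.0476, 0.0491 and 0.026), 3 of 13 in the early list and 1 of 8 in the late list, with equal counts adjusted over the list alone, beside the 164 lower genes of the chromosome. The late control gene Cdh11 was lower for RexTrim minus Trim (-1.04) adjusted over the list alone. Under rescaling 11 of the 13 early and 4 of the 8 late control genes were lower, among them Junb (-1.42) and Prdx2 (-1.44), and 6 and 1 were with both alleles averaged. Quantile normalization ended the control calls (0.0575 to 0.5921), though Calr (-1.14) and Dnase2a (-0.90) kept their size while Gins2 (-0.22) and Sntb2 (-0.78) shrank. The calls also ended on leaving out RexTrim D8 (0.0843 to 0.2055) or Rex1 D1 (0.0797 to 0.1399). Leaving out RexTrim D3 ended those of Dnase2a, Gins2 and Sntb2 (0.0622 to 0.1986), and leaving out Rex1 E3 that of Gins2 (0.0632). Sntb2 was listed as late but scored 1.91 and 3.07 in the compared genotypes.

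Comparisons with the Rex1 clones also called many windows over 2 Mb from the edits. RexTrim minus Rex1 had 128 higher and 35 lower svim windows, 154 of them far, though more genes were lower than higher, and Rex1 minus Trim had 21 higher and 106 lower, 107 of them far. RexTrim minus Trim had 19 lower and 0 higher windows on svim. These splits changed with the scaling: after rescaling they were 88 higher and 1488 lower for RexTrim minus Rex1, and 410 higher and 94 lower for Rex1 minus Trim. On cast, where RexTrim minus Rex1 had 0 windows as deposited, rescaling gave 29 higher and 1061 lower. RexTrim minus Rex1 had 0 windows without Rex1 D1, 299 higher and 78 lower without Rex1 E3, and 41 and 15 without RexTrim D8. Rex1 minus Trim had 5 windows without Trim E9, 3 higher and 15 lower without Trim D9, and 24 and 269 without Rex1 E3. The largest far differences of RexTrim minus Rex1 were 2.66 in the window from 96300001, 2.64 from 108000001 and 2.62 from 107950001, where no protein-coding gene lies. Those of Rex1 minus Trim included -2.52 from 85900001 and -2.49 from 85950001, both over Phkb, which encodes a subunit of phosphorylase kinase. On cast, Rex1 minus Trim had 5 higher and 14 lower windows, all 19 far, and 250 and 21 after rescaling; the largest differences were 2.94, 2.90 and 2.86 in 3 neighbouring windows from 87550001 that overlap 4933402J07Rik and the zinc finger gene Zfp423. It had 0 without Trim D9, 2 and 0 without Rex1 D1, 9 and 124 without Rex1 E3, and 2 and 39 without Trim E9. RexTrim minus Rex1 and RexTrim minus Trim had 0 cast windows (limma; 608 and 100 at an unadjusted p under 0.05), which became 130 and 8 without Rex1 E3 and 0 and 28 without Trim E9.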

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

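No test in this part was chosen after the result was seen, because the differences here were not tested.

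The deletion of 435 kb had opposite signs in non-hybrid cells and, as deposited, on cast in cas/129 cells. The non-hybrid domain differed from 46C by -1.80, and the cast domain of 435kdel B8 from the comparison clones by 0.11 (0.1055 before rounding). The cast value turned to -0.13 without comparison clone 24.5kinv 3 and to -0.15 under rescaling, where the signs agree. On svim, the only column blank inside the deletion, 435kdel B8 differed by -0.87, the sign of the non-hybrid value. Each side has 1 clone, and the difference between them was not tested.

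The deletion of 680 kb also had opposite signs in non-hybrid cells and on svim in cas/129 cells. The non-hybrid clones differed from 46C by -3.48, and the svim domain of 680kdel 79 from the comparison clones by 0.56 (0.5602 before rounding). Its cast domain differed by -2.97, the sign of the non-hybrid value. These values cover the 8 domain positions outside the deletion. The difference between the backgrounds was not tested. Non-hybrid profiles do not separate alleles, the cultures differed, and in clone 79 the positions inside the deletion are blank in cast alone. The opposite sign thus lies on the allele whose positions inside the deletion hold values.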

How the results depend on the processing

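Tests chosen after the result was seen were the adjustment over the domain tests alone, the comparison of changed windows by length in kb, and the choice to print lengths per genotype only where the main length is above 0. Across genotypes, no paired analysis was possible because the replicate numbers count the clones, or the repeats of a clone, within each genotype; the alleles of a clone were compared within it. Unless a reason is given, the cause was not tested. Depth is unknown, so what it limits cannot be stated; a left-out clone can leave 1 clone, which is assumed to vary like the others.

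The abc.del difference on svim stayed past the threshold in 20 of 20 alternatives with a test, from -5.12 to -3.44 with adjusted p up to 0.0035. The ab.del difference stayed past it in 17 (adjusted p up to 0.6043) and the ac.del difference in 18 (up to 0.5381). Of the 68 comparisons with 0 changed windows, 30 had some under an alternative, from 50 to 54500 kb.

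Rescaling gave ab.del -2.47 (adjusted p 0.6043) and ac.del -2.95 (0.1912), with 0 kb of changed windows in ab.del, ac.del and c.del (650, 650 and 250 kb as deposited). It left 1 cas/129 domain call of 3 and 600 kb of 2250 kb. On chromosome 8 it gave 78800 kb for RexTrim minus Rex1 on svim (8150), 25200 kb for Rex1 minus Trim on svim (6350), 13550 kb on cast (950), 173400 kb in all (16400), and RexTrim minus Rex1 of -1.65 on cast (0.0303). Svim minus cast of 18kdel relative to the comparison clones became -0.89 (-0.76 as deposited; exact permutation p 0.0476), and C57BL minus svim 1.60 in 435kinv A4 (1.01) and -1.02 in 18kdel H5 (-0.54).

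Quantile normalization gave c.del 0 kb, Rex1 minus Trim on cast 3450 kb with 47 higher and 22 lower windows, and an abc.del departure from additivity of -4.22 (adjusted p 0.0294), the 1 departure called under it. Svim minus cast relative to the comparison clones became -1.47 in 145kdel, -1.86 in 435kdel, -1.04 in 18kdel (exact permutation p 0.0476) and -0.84 in 4kdel (0.0952). NPC minus mESC became -5.33 on svim and -5.72 on cast. With repeats as separate samples the abc.del departure was -3.66 (0.0406), again the 1 departure called.

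With trend and robust settings the domain passed in 345kdel (-4.03, adjusted p 1.12e-08) and 680kdel (-3.48, 1.89e-08) of the non-hybrid cells, 2 calls in place of 0, and on cast in 680kdel 79 (-2.97, 0.0074). Changed windows came to 2200 kb in 500kdel (100), 8400 kb over the non-hybrid edits (100), 29100 kb for RexTrim minus Rex1 and 17350 kb for Rex1 minus Trim on svim, 12750 kb on cast, and 77800 kb over chromosome 8. With 100 kb windows 345kdel (-4.03, 0.0323) and 680kdel (-3.48, 0.0392) also passed, 2 calls in place of 0, with 500 kb of changed windows. Fewer windows share the correction there.

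With the adjustment over the domain tests alone, fewer tests share the correction. It called 5 cas/129 domains, among them 680kdel on cast (-2.97, 0.0062) and 4k.b.c.del (-1.92, 0.0401). It called 3 non-hybrid domains (345kdel -4.03, 5.51e-04; 680kdel -3.48, 9.90e-04; 435kdel -1.80, 0.0469) and 3 departures from additivity on svim (ab.del -2.22, 0.0157; ac.del -1.83, 0.0232; abc.del -3.43, 0.0044).

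With the 30kdel clones alone for comparison, 6 cas/129 domains passed, among them 145k.30kdel (-1.40, adjusted p 0.0379), 4k.b.c.del (-2.17, 0.0082) and 680kdel on cast (-2.93, 2.73e-05). Changed windows came to 3100 kb in ab.del, 2050 kb in abc.del (700), 1150 kb in ac.del and 56600 kb in all. Against the median of the other genotypes, with no test, svim differences were -4.21 in abc.del, -2.21 in ab.del, -2.27 in ac.del, -1.26 in 4k.b.c.del, -0.68 in 145k.30kdel, -0.64 in 145kdel, -0.64 in 18kdel, -0.61 in 435kinv, -0.57 in 680kinv, -0.42 in bc.del, -0.33 in 435kdel, -0.21 in 28kdel and -0.083 in 4kdel. They were 0.058 in c.del, 0.14 in 28.5kdel, 0.27 in 4k.b.del, 0.32 in a.del, 0.36 in b.del, 0.47 in 100kdel, 1.01 in 680kdel, 1.02 in 28.5kinv and 1.57 in 245kdel.

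Leaving out 25 kb beside deletions gave 400 kb in abc.del, 100 kb in c.del and 1400 kb in all cas/129 edits, and svim minus cast, here relative to the comparison clones, of -0.80 in 18kdel (-0.76 as deposited; exact permutation p 0.0476). A narrower domain gave -0.81 there (0.0476). A wider domain gave, again relative to the comparison clones, -0.88 in 18kdel (0.0476), -0.67 in 145k.30kdel (-1.12 as deposited; 0.1429), -0.56 in 145kdel (-0.998), -0.76 in 4k.b.c.del (-1.57), -0.19 in 435kinv (-1.04) and an unsigned 0.18 in 680kinv (0.4821). It also turned C57BL minus svim of 435kinv A4 to -0.039, and gave NPC minus mESC of -5.19 on svim and -5.67 on cast. Averaging the chromosome 8 alleles gave Rex1 minus Trim of -0.88 (adjusted p 0.1282) with 3050 kb, RexTrim minus Rex1 3700 kb and RexTrim minus Trim 300 kb (950).

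With each clone left out, the domain difference ran from -2.99 to -2.70 in ab.del (-2.74 without D10, adjusted p 0.072) and from -3.74 to -2.11 in ac.del (0.5381 without H8). It ran from -2.04 to -1.75 in 4k.b.c.del and from -3.16 to -2.75 in 680kdel on cast, both past the threshold without 24.5kinv 3 (0.0212 and 0.0305). It ran from -4.22 to -2.64 in the abc.del departure (0.0428 without a.del G5). On chromosome 8 it ran from -2.43 to -2.21 for Rex1 minus Trim (-2.33 without Trim E9, 0.0683) and from -2.22 to -1.88 for RexTrim minus Rex1 (-1.94 without Rex1 D1, 0.0554). Changed windows ran from 250 to 750 kb in ab.del (250 without D10, 300 without D12, 400 without 30kdel B11 or C2), from 0 to 950 kb in ac.del (0 without H8) and from 0 to 250 kb in c.del (0 without A12, B11 or 30kdel C2, 100 without C9 or 30kdel B11). On svim they ran from 0 (without D1) to 18850 kb (without E3) for RexTrim minus Rex1, with 2800 kb without RexTrim D8. For Rex1 minus Trim they ran from 250 (without E9) to 14650 kb (without E3), with 900 kb without D9. On cast they ran from 0 (without D9) to 6650 kb (without E3), with 100 kb without D1 and 2050 kb without E9.

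Svim minus cast relative to the comparison clones ran from -1.25 (without C6) to -0.54 (without G4) in 4kdel, from -0.41 (without 53) to 1.06 (without G5) in a.del, from -2.78 to -2.04 in ac.del, and from -2.25 (without 80, exact permutation p 0.0476) to -0.030 (without B10) in 680kinv. Over the listed genes of the comparisons rechecked, 1821 gene tests under the alternatives kept their side of the threshold, 95 calls were lost and 68 gained. The 1821 include genes called neither in the main fit nor under the alternative, so they give no share of calls kept.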

Other observations

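Tests chosen after the result was seen were those of the Rex1 windows far from the edits and of the number of intervals lost, over clones and over genotypes; the segment described first was also chosen after its values were seen.

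The segment left of the 350kdel, from 47712071 to 47900058, replicated late in 46C, with a score of -3.11. In non-hybrid cells it scored 0.10 in 350kdel and -0.56 in 435kdel, and between -4.01 (245kdel 28) and -1.84 (a 45kinv repeat) in the other edits with values there, with -2.04 and -2.53 in the 680kdel clones 13 and 16 and -3.07 in 350kinv. In cas/129 cells it scored -0.08 on svim in 435kdel B8, against -1.64 on cast, and -2.07 and -1.22 in 680kdel 79. The long inversions gave a similar contrast: on svim the segment scored 0.05 in 435kinv C5, 0.16 in 680kinv B10 and -0.71 in 680kinv C5, against -2.34, -1.44 and -2.21 on cast, and in 680kinv 80 it scored -3.38 on svim and -0.38 on cast. In the cas/129 mESC profiles without a 435 kb or 680 kb edit, svim ran from -3.78 to -1.43 and cast from -3.47 to -0.90, the highest being 24.5kinv 3 on both. In v6.5 435kinv A4 it scored -0.80 on svim and -3.05 on C57BL. No test was made of this segment.

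A hypothesis on the deletions is that the domain score on svim may fall with the number of the intervals a, b and c that the labels place in a clone's deletions. Over 33 cas/129 deletion clones, Spearman's rho was -0.46 (permutation p 0.0076, 0.015 after Benjamini-Hochberg adjustment over both alleles) and Pearson's r -0.64 (permutation p 8e-05, adjusted 0.00016). These p-values exchange clones, while the number is fixed for a genotype; over the means of 19 genotypes rho was -0.38 (permutation p 0.11), and -0.53 (0.026) without 680kdel, whose blank positions lie in cast. The clones are those whose abc.del, ab.del and ac.del values raised the hypothesis. Without the 2 clones farthest from the median, r was -0.39 (permutation p 0.031) and rho -0.33 (0.068), so the rank relation rests partly on those clones. Median differences were -0.96 with 0 intervals lost (4 clones), -0.64 with 1 (19), -2.01 with 2 (8) and -4.88 with 3 (2). The correlations and medians leave out the deletion clones used for comparison (30kdel B11 and C2, 29kdel D8, 14kdel D11), which also lose 0 intervals. Their svim scores of 1.89, 2.74, 1.83 and 2.35 lie around the comparison mean of 2.09. The medians therefore do not settle how the score moves from 0 to 1 interval lost. On cast rho was 0.03 (0.0306 before rounding; permutation p 0.87), which decides nothing, because only 1 of the 33 clones is blank in the cast column.

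The a.del clones 53 and G5 differ on svim (2.48 and 0.93). An offset of a whole allele column is argued against, because the median of svim minus cast outside 5 Mb differed between the clones by 0.051, far less than their gap. Swapped allele columns in clone 53 are argued against, because svim minus cast along the chromosome correlated with the comparison clones at 0.79 (across windows), where a swap gives a negative value. The design gives no biological explanation to test, and a difference between the clones' edits was not tested and stays open. Values inside interval a in both columns do not settle it. The svim columns of ab.del, ac.del and abc.del also held a value at 1 position inside their edits.

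The later allele is cast in 680kinv 80 and svim in B10 and C5. Swapped allele columns in clone 80 are argued against by a correlation of 0.701 with the comparison clones outside 5 Mb, and an offset of the column by a median difference of 0.0702. An inversion on the other allele in clone 80 was not tested, because the labels name no edited allele and an inversion leaves no blank positions.

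The Rex1 clones differ from the RexTrim and Trim clones in 261 far windows on svim, summed over both comparisons. A difference in scaling between libraries stays open as a cause: 253 far windows were called after quantile normalization and 1976 after rescaling. A count near 261 does not show that the same windows remained. Whether 1 library, Rex1 D1, makes the pattern is open: 82 windows were past the threshold without D1 and 638 without E3. Far from the edits D1 had a median of -1.02 on svim and -1.18 on cast, outside the range of -0.49 to 0.13 of the other columns. A biological effect of the Rex1 deletion was not tested and stays open.

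Other splits of the same clones were counted where a genotype has at least 3 clones. For c.del on svim, 1 of 100 drawn splits, the real one, gave as many changed windows (5, highest other 0). For the profiles as deposited this argues against a chance split, and with 100 splits it cannot exclude one. The same comparison gave 0 kb after rescaling, after quantile normalization, and without A12, B11 or comparison clone 30kdel C2. For c.del on cast (all 100 splits; highest other 0) and for 680kinv on svim (all 56; highest other 11) and cast (all 56; highest other 15) the real count is 0, which every split reaches, so these counts decide nothing. Some 680kinv splits called windows where the labels called 0; what sets those clones apart was not tested.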
